A study of Trifolium repens with 6 samples.

How the data were processed

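Petal RNA of a red-flowered mutant of white clover (Trifolium repens, a legume with an allotetraploid genome) was sequenced from plants left in the open field and from plants of the same mutant kept under a shading net from before flowering. The labels give 3 libraries per condition and record red petals for the field group and white petals for the shaded group. The groups were taken from the source labels, and the replicate numbers 1 to 3 from the sample titles. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

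The submitters' processing notes name RSEM 1.2.12 and DESeq. The assembly that gave the unigenes, the aligner and the read filters are not given in the sources used here. Each library has its own table of unigene ID, length, expected count and FPKM, per the file headers. The expected count is RSEM's estimated count of reads per unigene, deposited without normalisation and not always whole, because RSEM divides a read that matches several unigenes among them. The FPKM deposited by the authors is normalised for length and library size. No listed unigene had an expected count of 0 in these tables, and a unigene missing from one table was taken to have 0 reads there. The 6 tables together held 152107 unigenes, each with the same length wherever it was listed. IDs are of 2 kinds, those with a CL number and a contig number, taken here as contigs of one assembly cluster, and those of single unigenes. The deposited tables do not pair the IDs with gene names or functions, and no genome or annotation was used here. Pathways, including anthocyanin synthesis, could therefore not be examined, none of the gene lists fixed beforehand was tested, and genomic positions are not given.

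The summed expected counts per library ranged from 14221859 to 20414104. Effective length was computed from the ratio of expected count to FPKM for unigenes with over 200 expected counts. Length minus effective length had a median of 166.1, 168.4 and 227.9 bases in field replicates 1 to 3 and of 163.1, 204.6 and 210.9 bases in shaded replicates 1 to 3. This quantity depends on the fragment length of a library, so field replicates 1 and 2 and shaded replicate 1 were treated as a short-fragment class and the other 3 libraries as a long-fragment class, divided at 180 bases. The classes cross the 2 conditions and were used as a possible technical batch in added comparisons, not in the main fit. The labels do not say whether they mark a batch. An FPKM of a unigene not much longer than the fragments rests on a very short effective length, so few reads can give a high value in the long-fragment class.

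Expected counts were rounded to whole numbers. Unigenes were filtered with filterByExpr at its count minimum of 10, which left 46778, and were tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, robust quasi-likelihood test, two-sided) for shaded against field over all 6 libraries without a covariate. Calls had a Benjamini-Hochberg adjusted p under 0.05, and a second count also required a 2-fold change. CPM values are TMM-scaled. The standard error of a log2 fold change was taken from log2 CPM (prior count 2) of the 3 libraries per group, and is given only for abundant unigenes, since the prior count narrows it where counts are few. Folds of named unigenes carry a 95% Clopper-Pearson interval from the summed counts, which covers counting error only. Single values per library were compared with exact permutation tests, two-sided, for which 3 against 3 libraries allow no p below 0.10, with Benjamini-Hochberg adjustment over the 12 tests made. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for these.

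Named unigenes followed a rule fixed before the data were examined, as were the main tests and all alternatives not described as added. With only assembly IDs to go by, the 2 smallest adjusted p-values per direction were taken (ties by unadjusted p) among unigenes changed at least 2-fold, with a mean FPKM of at least 1 in the higher group and no overlap between groups.

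The edgeR procedure was tested on simulated counts with 200 changed unigenes, of which 195 passed the filter among 43427 tested. It recovered 0 of 48 changes of 2-fold, 4 of 49 of 4-fold, 19 of 49 of 8-fold and 39 of 49 of 32-fold, with median fitted log2 sizes of 0.98, 2.02, 2.94 and 5.11. Of 66 calls, 4 were unchanged unigenes, and counts simulated without any change gave 2 calls. The real libraries gave 4795 calls, far more than the 200 changes simulated. With so few changes the Benjamini-Hochberg cut-off is stricter, so the recovered shares are not the sensitivity of the real comparison. Libraries of one group differed far beyond sampling noise (chi-square per degree of freedom of at least 26.3), so none was a duplicate of another.

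The labels do not say that equal replicate numbers mark a shared plant or day, and the libraries were not treated as pairs. Alternatives were DESeq2 size factors, other filters, the DESeq2 1.42.0 Wald test, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, removal of unigenes under 500 bases, and leaving out each library. The fragment class as a covariate, cluster sums, count thresholds and thinning were chosen after seeing the data.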

Results

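The petal transcriptome of the red-flowered white clover mutant was compared between plants in the open field, with red petals, and plants under a shading net, whose petals were white. The comparison addresses which petal transcripts differ when plants of this mutant are kept under a shading net, and does not separate light at the flowers from other effects of the net. There were 3 libraries per condition. Total expected counts were 14221859, 17360540 and 17369632 in field replicates 1 to 3 and 20414104, 17169493 and 16979740 in shaded replicates 1 to 3. Transcripts are assembled unigenes without gene names, so groups of unigenes are described by level, length, cluster and size of change.

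The libraries separated by condition. Over 57794 unigenes with FPKM of at least 1 in at least 3 libraries, Pearson's r of log2(FPKM + 1) was 0.81 to 0.88 for the 6 pairs within a condition and 0.63 to 0.74 for the 9 pairs between conditions. The lowest value within a condition, between field replicates 1 and 3, was above the highest between conditions. Within a fragment class, r was 0.871 and 0.868 for the 2 pairs of one condition and 0.633 to 0.743 for the 4 pairs between conditions. These correlations run across unigenes, which are not independent replicates.

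**Figure D1:**
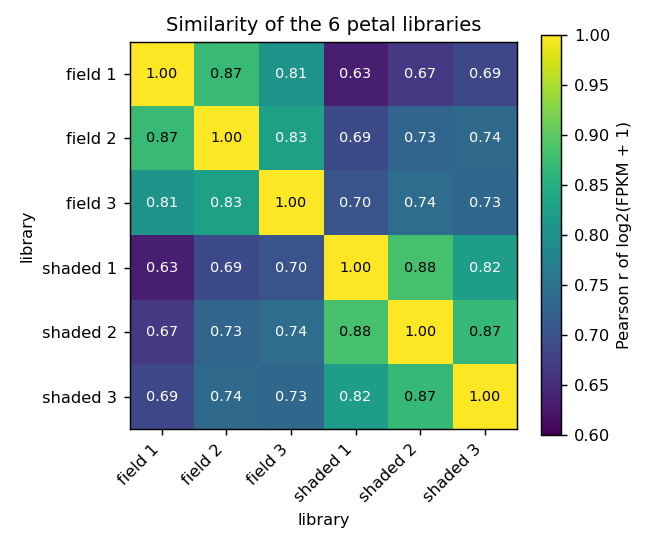
Pearson's r of log2(FPKM + 1) between each pair of the 6 libraries, over 57794 unigenes; both axes list the libraries and colour gives r. Pairs within a condition reach 0.81 to 0.88, and pairs between conditions 0.63 to 0.74.

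Shading went with a wide change in petal transcripts. Of 46778 unigenes tested, 4795 (10.3%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. 2210 were higher and 2585 were lower in the shaded petals. Nearly all changed at least 2-fold, 2105 of those that rose and 2503 of those that fell. The median fitted log2 fold change was 2.33 for the unigenes that rose and -2.81 for those that fell. Of these, 133 and 246 unigenes had no count in the other condition, and with them set to a floor of 3 counts per library the medians were 2.28 and -2.72. With that floor, 1298 unigenes were at least 4-fold higher and 1785 at least 4-fold lower, and 378 and 690 passed 16-fold. The median over all tested unigenes was -0.02. With 3 libraries per condition, small changes pass the test less often than large ones, and 0 of 48 simulated changes of 2-fold were recovered. The sizes of the called changes therefore follow partly from their selection and do not give the usual size of change under shade.

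The unigenes that rose took up 3.43% ± 0.68 (SD, n = 3) of all counts in the field libraries and 14.7% ± 2.57 in the shaded libraries. Those that fell took up 13.1% ± 1.13 in the field and 3.37% ± 0.42 under shade. These sets were chosen by their change in the same libraries, so the shares describe their weight and are not a separate test. Among the 100 most abundant unigenes by mean CPM, 15 rose, 12 fell and 73 did not pass the test. The most abundant unigene that rose, 768 bases long, went from 1261 ± 302 to 3361 ± 611 CPM (SD, n = 3; log2 fold change 1.41 ± 0.27 SE, adjusted p = 0.042 in edgeR). The most abundant that fell, 1465 bases long, went from 4958 ± 461 to 1960 ± 243 CPM (log2 fold change -1.34 ± 0.13 SE, adjusted p = 0.035 in edgeR).

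The count of called unigenes fell whichever library was left out, by amounts that differed between libraries. Each such fit also has fewer residual degrees of freedom, so lost power and the influence of a library are mixed. With 5 libraries the count was 690 without shaded replicate 2, 1153 without shaded replicate 1, 1672 without field replicate 1, 1955 without field replicate 2, 3025 without shaded replicate 3 and 4096 without field replicate 3. The count was 2315 with the fragment class as a covariate, 8218 with limma on log2(FPKM + 1), and 9238 with the DESeq2 Wald test, which called 4794 of the 4795. With no filter on low counts it was 10417 of 152055 unigenes, but these included only 4514 of the 4795.

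**Figure D2:**
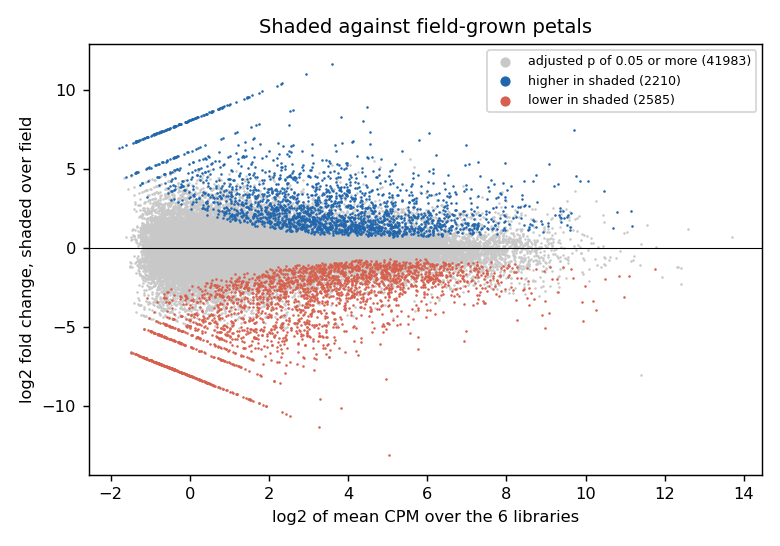
Log2 fold change of shaded over field petals (vertical axis) against log2 mean CPM over the 6 libraries (horizontal axis), one point per tested unigene; blue marks the 2210 called higher and red the 2585 called lower. The straight diagonal bands at the left are unigenes with 0 or very few counts in one condition, whose fitted fold depends on the prior count.

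Changes were seen at every level of expression and at every length. In the lowest quartile of mean CPM (0.292 to 1.38), 251 unigenes rose and 441 fell, 5.9% of the quartile. In the highest quartile (above 13.4 CPM), 942 rose and 942 fell, 16.1% of the quartile. The share of calls that were higher in shade was 36.3% in the lowest quartile and 50% in the highest. By length, that share was 36.4% among unigenes of up to 907 bases, where 403 rose and 704 fell, and 51.2% among those longer than 2020 bases, where 678 rose and 647 fell. The median log2 fold change lay between -0.056 and -0.003 in all length quartiles. Cluster contigs and single unigenes both changed in each direction, with 1445 higher and 1572 lower among 32076 contigs, and 765 higher and 1013 lower among 14702 single unigenes.

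The 4 unigenes with the smallest adjusted p per direction differed between conditions by 27.8 to 530.9 times in summed counts scaled for library size. The intervals given with these ratios are 95% and cover counting error only. Unigene43710_All (671 bases) had the smallest adjusted p among those that rose, with 0.08 ± 0.03 CPM in the field and 44.3 ± 7.01 CPM under shade (SD, n = 3). Its fitted log2 fold change was 8.92 (adjusted p = 0.00164, edgeR), a value that rests on few field counts. It had 4 counts in all field libraries together and 2462 in the shaded libraries, a ratio of 530.9 with a counting interval of 207.1 to 1950. CL13952.Contig1_All (1185 bases) rose from 0.81 ± 0.14 to 44.0 ± 4.17 CPM, 54.8 times (39.8 to 77.6), with adjusted p = 0.00171 in edgeR. CL17675.Contig2_All (557 bases) fell from 15.6 ± 2.85 to 0.43 ± 0.04 CPM, a field-to-shade ratio of 35.1 (23.4 to 55.1), with adjusted p = 0.00356 in edgeR. CL9405.Contig2_All (1194 bases) fell from 18.6 ± 3.86 to 0.66 ± 0.05 CPM, a ratio of 27.8 (19.9 to 40.0), also with adjusted p = 0.00356.

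Contigs of one cluster can share reads, which RSEM divides, so the level of a single contig is uncertain where its cluster holds others. CL13952.Contig1_All held 40.2% of its cluster's counts in shaded petals, and the summed cluster of 2 contigs rose by a log2 fold change of 4.72 (adjusted p = 0.00196, edgeR). CL17675.Contig2_All held 99.2% of its cluster's counts in field petals, and its cluster changed by -5.15 (adjusted p = 0.00151, edgeR). For CL9405.Contig2_All the share was 67.0% of a cluster of 3 contigs, which changed by -4.52 (adjusted p = 0.00205, edgeR).

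**Figure D3:**
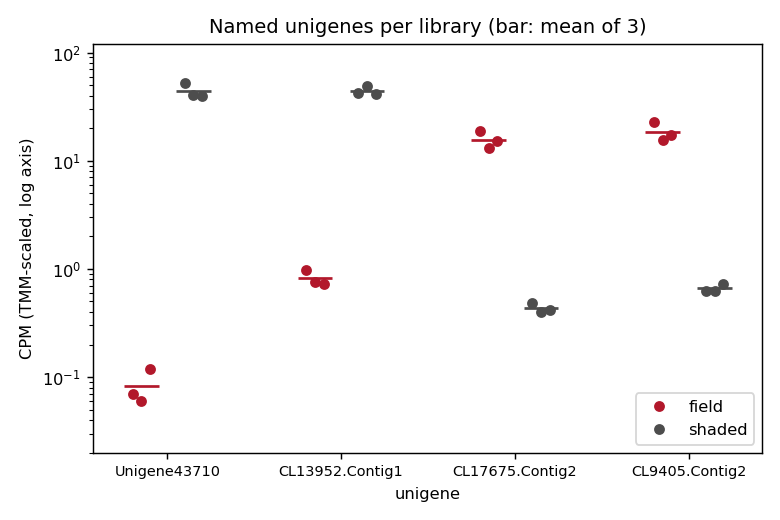
CPM (log axis) of the 4 named unigenes in each of the 3 field libraries (red) and 3 shaded libraries (grey); bars are group means. Unigene43710 and CL13952.Contig1 lie near 44 CPM under shade and below 1 CPM in the field, and the other 2 unigenes lie between 13 and 23 CPM in the field and below 1 CPM under shade.

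The difference between conditions was also computed within each fragment class. The short-fragment class had 2 field libraries and 1 shaded library, and the long-fragment class had 1 and 2. Over the 46778 unigenes the log2 fold changes of the classes, which share no library, correlated with r = 0.44 and rho = 0.50, and 68.6% had the same sign. These values are across unigenes, which are not independent replicates. In each class 1 condition had a single library, whose spread cannot be measured. Effect sizes alone are therefore given within the classes, and they do not test any unigene. Unigene43710_All had log2 fold changes of 9.45 and 8.27 in the short and long classes. CL13952.Contig1_All had 5.56 and 5.92, CL17675.Contig2_All -5.07 and -5.20, and CL9405.Contig2_All -4.97 and -4.70.

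Some unigenes were seen in one condition only. 684 unigenes had FPKM of at least 1 in all 3 shaded libraries and under 0.1 in all 3 field libraries, and 1412 had the opposite pattern. At the same thresholds, the largest count among the other 18 ways of setting 3 libraries against the rest was 319. Each of these ways has both conditions on both sides, so a unigene that follows the condition cannot be counted in them. The 319 therefore does not show how many would arise without any difference. With FPKM of at least 2 in place of 1, the counts for the real conditions were 214 and 407, and the other ways were not counted. The 684 and 1412 unigenes were mostly short and low, with median lengths of 299 and 333 bases and median FPKM of 2.80 and 2.71 in the condition where they were present. A mean FPKM of at least 10 was reached by 13 of the shaded-only and 47 of the field-only unigenes, and the highest were 16.6 and 39.8. Only 128 and 276 of them had enough counts for the edgeR test, of which 128 and 275 were called. They were chosen by their levels in the same libraries, so this share of calls follows from the selection and is not a separate test. With one shaded library left out, 1963 to 2070 unigenes were shaded-only, and with one field library left out, 3652 to 4210 were field-only, as fewer libraries had to meet the condition.

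More unigenes were detected in field petals. FPKM of at least 1 was reached by 70004 ± 4988 unigenes (SD, n = 3) in the field libraries and 60445 ± 2778 in the shaded libraries, with no overlap between conditions. The exact permutation test gave p = 0.1, two-sided, the smallest these 6 libraries allow (0.20 after Benjamini-Hochberg adjustment over 12 tests). The shaded-minus-field difference was -9820 in the short-fragment class and -13519 in the long-fragment class. Fragment length was not equal within the long class. Its field library had a length minus effective length of 227.9 bases, against 204.6 and 210.9 in its shaded libraries. Longer fragments can raise the FPKM of short unigenes, so the larger difference there may be partly technical. Unigenes with a rounded count of at least 10 numbered 47253 ± 1572 in the field and 46649 ± 2307 under shade, a difference within the spread between libraries (exact permutation p = 0.8, two-sided, 0.80 adjusted). This threshold was chosen after seeing the data, and the difference had opposite signs in the short and long classes, 2113 and -2054. At FPKM of at least 5, the numbers were 25507 ± 6961 and 22406 ± 2395 (exact permutation p = 0.7, two-sided, 0.76 adjusted).

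**Figure D4:**
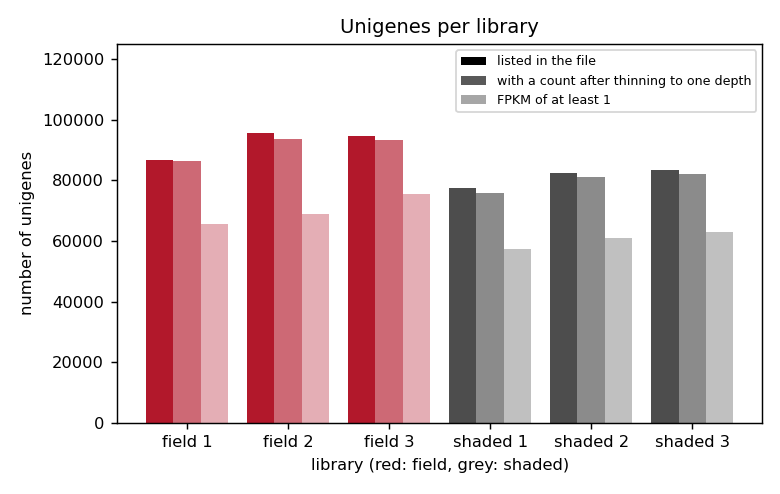
Number of unigenes per library that were listed, had a count after all libraries were thinned to 14221865 counts, or had FPKM of at least 1; red bars are field and grey bars shaded libraries. By each measure every field library lies above every shaded library.

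The share of reads on the most abundant unigenes was compared with the same test, in which no difference between these 6 libraries can give a p below 0.1. The 10 most abundant took 6.65% ± 1.08 of the counts in the field libraries and 5.55% ± 0.59 in the shaded libraries (SD, n = 3; exact permutation p = 0.2, two-sided, 0.30 adjusted), with differences of -1.04 points in the short class and -0.19 points in the long class. The 100 most abundant took 18.7% ± 2.16 and 17.7% ± 0.81 (exact permutation p = 0.6, two-sided, 0.72 adjusted), with differences of -1.32 and 0.96 points in these classes. Over all libraries the differences were -1.10 points for the top 10 and -1.03 points for the top 100. Without field replicate 3 they were -1.72 and -2.25 points, and for the top 100 the difference was -0.62 points without field replicate 1 and -0.21 points without field replicate 2. Measured on FPKM, the shares were 2.25 and 2.43 points higher in shaded petals, the opposite sign, with exact permutation p of 0.2 and 0.3 (0.30 and 0.40 adjusted). Within the short and long classes the FPKM differences were 3.21 and 2.04 points for the top 10, and 2.63 and 4.34 points for the top 100.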

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

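The fragment class covariate, cluster sums, count thresholds and thinning were chosen after seeing the data. The 2210 higher and 2585 lower calls stayed within 1.5 times with DESeq2 size factors, an FPKM filter, limma on log2(FPKM + 0.1), cluster sums and without unigenes under 500 bases. With no filter on low counts, 10417 unigenes were called (4349 higher, 6068 lower), of which 9884 changed at least 2-fold (4119 and 5765). They included 4514 of the 4795. In that fit the edgeR adjusted p of Unigene43710_All went from 0.00164 to 1.83e-70 at a similar log2 fold change of 8.94. The unfiltered p-values and count are therefore not on the scale of the main fit. The DESeq2 Wald test called 9238 (4243 and 4995), or 8301 at 2-fold (3755 and 4546). Limma on log2(FPKM + 1) called 8218 (3903 and 4315), or 7819 at 2-fold (3666 and 4153). The fragment class covariate gave 2315 (1099 and 1216), all at least 2-fold, of which 2226 were among the 4795. The cause of these shifts was not tested. The labels do not pair the libraries. With the replicate number as a block, which leaves fewer residual degrees of freedom, 371 were called (147 and 224), all at least 2-fold. Deviations of same-numbered libraries from their group means correlated at -0.01, 0.01 and -0.09, and no field library correlated best with its own number. Leaving out one library also leaves fewer residual degrees of freedom. It gave 690 to 4096 calls (282 to 2167 higher, 408 to 1929 lower), and 690 to 4066 at 2-fold (282 to 2150 and 408 to 1916). The lowest came without shaded replicate 2 and the highest without field replicate 3. The 4 named unigenes stayed called in the same direction in all alternatives in which they were tested, with edgeR, DESeq2 or limma adjusted p of at most 0.0432. They were picked for the smallest adjusted p in these same libraries, so this was largely set by their selection and is not separate support. At FPKM of at least 2 in place of 1, 214 unigenes were shaded-only and 407 field-only. At FPKM of at least 1, where all 6 libraries gave 684 and 1412, the counts without one library were 886 to 2070 and 1704 to 4210, as fewer libraries had to meet the condition. The mean within-condition r exceeded the between-condition r by 0.144, by 0.188 with Spearman's rho and by 0.194 with a pseudocount of 0.1. The difference in the share of the most abundant unigenes reversed with FPKM, to 2.25 (top 10) and 2.43 (top 100) points higher in shade. The shaded-minus-field difference in the number of unigenes with FPKM of at least 1 was -6833 to -11726 without one library. It was -605 at a count of at least 10, within the spread between libraries and with the opposite sign in the short-fragment class (2113). The counts behind that threshold were not thinned, so depth is mixed into it. Gene list settings were not run, as the unigenes carry no names. At this depth, 30.8% of the 152107 unigenes had enough counts to be tested, and the calls do not cover the others.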

Other observations

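The tests of contig directions, of contigs leading in one library, and of fragment length as a source of the higher number of unigenes in field libraries were chosen only after the result was seen. Contigs of one cluster changed together. Of 9856 clusters with at least 2 tested contigs, 546 had at least 2 contigs called. In 519 of these (95.1%) all called contigs moved the same way, and in 27 they moved in both directions. Permuting the directions over all called contigs gave 240.9 such clusters on average and 291 at most (p = 0.0001 from 10000 permutations, the smallest they can give). RSEM divides shared reads among similar contigs, which ties their counts to some degree, so contigs of a cluster are not independent. The permutation treats them as unrelated, so its p does not separate changes of distinct contigs from reads they share.

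One abundant cluster, singled out after its values were seen, was carried by another contig in a single library. CL5074.Contig6_All (7059 bases) was the most abundant unigene in field replicate 2 and in all 3 shaded libraries, with 1.34% to 2.12% of the counts. In field replicate 3 it held 0.421%, while CL5074.Contig4_All (6838 bases) held 1.54%, against 0.001% to 0.003% in the other 5 libraries. The whole cluster held 1.97% in field replicate 3 and 0.86% to 2.13% elsewhere. Of 3475 clusters with at least 20 CPM in every library, this was the only one in which a contig with at least 50% of the cluster in one library had under 5% in each of the others.

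The other splits of the 6 libraries into 3 and 3 gave no calls in edgeR, against 4795 calls and 4608 at 2-fold for the real split. Only 1 of the 10 splits, the real one, reached these counts. At an unadjusted p under 0.05 the highest of the other splits gave 2476 unigenes and the real one 12763. Each of the other splits puts libraries of both conditions in each arm, so the difference between conditions adds to the spread within an arm. They therefore do not show how many calls would arise without any difference. 10 splits are also too few for a share under 0.05.

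More unigenes had reads in the field libraries (92374 ± 5014 listed, SD, n = 3) than in the shaded libraries (81069 ± 3230), although the deepest library was a shaded one. Depth is argued against: with all libraries thinned to 14221865 counts, the lowest field library still had 4491 more unigenes than the highest shaded library. The fragment length of the libraries is argued against by a gap of at least 9243 unigenes within each fragment class, and reads taken up by a few abundant unigenes by a gap of 4441 after the 1000 most abundant were left out and the rest thinned. In the long class the field library had the longest fragments, so the argument on fragment length rests more on the short class, where lengths were closer. Part of the excess lay in unigenes with a count in one library alone, which numbered 7158, 9120 and 14108 in field replicates 1 to 3 and 3884, 4333 and 5956 in shaded replicates 1 to 3, with median lengths of 233 to 240 bases and median counts of 3 to 5, and part in unigenes of one condition, as 4024 had a count in all 3 field libraries and no shaded library (median length 385 bases) and 1844 the reverse (362 bases). The growth condition itself, RNA from other organisms on open flowers, and how the assembly was built remain open as possible explanations, since the unigenes have no sequence or name here.

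Differences between replicates were compared with the difference between conditions. For each pair of replicates, the log2 CPM difference was correlated across 46778 unigenes with the shaded-minus-field difference made from the 4 remaining libraries, and the absolute r was 0.02 to 0.31, with a median of 0.18. With all libraries thinned to one depth, the median absolute r was 0.34 (0.03 to 0.52) over 13971 unigenes with mean CPM of at least 10. A correlation at equal depth argues against depth as the whole cause. The unigenes and the log transform also differed from the first computation, so 0.34 and 0.18 do not show the effect of thinning. Library fragment length as the whole cause is argued against by the 2 pairs of one class, with 0.14 and 0.18. The absolute r to be expected from unrelated replicate differences was not computed. It is therefore not known whether these values exceed it, which limits both arguments. If they do, a candidate explanation is that the flowers of one condition differed in stage or in the light they received. The labels give neither, and no biological explanation was tested.

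Unigenes present in one condition only could arise where reads move between contigs of one cluster. Of the 2096, 477 belonged to a cluster with at least 1 other contig with reads, and for 345 of these (72.3%, Wilson 95% interval 68.1% to 76.2%) the summed cluster also changed at least 2-fold the same way, which argues against this as the main source among them. For 121 (25.4%) the sum changed less than 2-fold and for 11 it changed at least 2-fold the opposite way, and for these it stays open. The summed cluster includes the selected unigene. The interval treats the unigenes as independent, although several can belong to one cluster.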
